A study of Solanum lycopersicum with 8 samples.

How the data were processed

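Leaves of tomato cultivar Summer sweet were sprayed with NPA or water and collected after 6 h or 12 h, and RNA pooled from 5 plants was hybridized to 1 array. The 8 arrays form 4 groups of 2, taken from the sample titles. The deposited table holds 1 value per probe set and array. Per the submitters' processing notes the values were made with RMA, whose version, background settings and filters are not given in the sources used here. The deposited values lie between 2.68 and 14.6 and were taken as log2 expression from that range and from RMA. No detection calls were used, so no probe set could be called absent. Every array column belonged to a sample.

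Of 8488 probe sets in the table, 84 controls were left out and 8404 tested. Platform annotation paired 753 of them with 1 gene symbol and 7651 with none, and 739 of the 753 gene identifiers were found in a RefSeq gene table of assembly SLM_r2.1. No build is named for the array, so no coordinates are given. Of 688 named genes 151 had only a LOC name and 49 had more than 1 probe set.

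Group means were fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual degrees of freedom, prior degrees of freedom 2.55, prior SD 0.163). Contrasts were NPA against water at 6 h, at 12 h and averaged, the difference of these effects, and 12 h against 6 h in water and in NPA. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The repeats were separate runs of the whole experiment, per the series design text. P-values measure the spread between these pools.

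Same-numbered arrays deviated together from their group means, with correlations across probe sets between 0.316 and 0.596 over 6 pairs of groups. The pairing rests on the design text, in which the whole set of experiments was repeated. The fit without the repeat is the main one, as set beforehand, and the fit with the repeat as a block is given where it changes a call or a count by over 1.5 times.

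Gene lists were tested with camera at a preset correlation of 0.01, using 1 probe set per named gene, the one with the highest mean, against the named genes. There were 29 fixed lists. Of these, 15 had at least 3 genes and were tested, and 7 had 1 or 2. The other 7 matched no gene: nitrogen and amino acid metabolism, sugar and starch, circadian clock, proteasome, senescence, flower and fruit markers, and root markers. Matching used gene symbols and synonyms, so an empty list does not mean that such genes were unmeasured. A further 12 lists were written after the gene symbols, and before any difference between groups, had been seen, and were adjusted as a family of their own. Camera with an estimated correlation and fry were run as alternatives.

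Named genes followed a rule set before the data were examined: up to 10 rises and 10 falls past the threshold at 6 h and at 12 h and 5 of each elsewhere, filled up to 5 by the smallest p among genes whose groups did not overlap, up to 4 members per list, and up to 2 unnamed probe sets per direction. Genes outside it are said to be so where they appear.

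The scripts were checked on simulated data for NPA against water at 6 h, with 200 changed among 8404 probe sets in each of 5 runs. Without the block, limma recovered 1.2% of changes of 0.5 on the log2 scale, 45.2% of changes of 1, 86.8% of 2 and 96.4% of 3, with 0.4 false calls per run. With the block these shares were 20.0%, 87.2%, 98.8% and 98.8%, with 10.2 false calls per run. The simulated spread was that of the block fit, and each change was the same in both repeats. Shares may be lower for genes whose effect differs between repeats. For lists, camera was tested on 100 simulated sets of 688 independent genes, and called 94 of the lists of 13 genes shifted by 1 SD and 3 of the unshifted ones at an unadjusted p under 0.05. This says nothing of its false calls for lists whose members vary together. The list of pathogenesis-related proteins had an estimated correlation of 0.781.

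Alternatives were another quantile normalization, centring, filters on dim probe sets, an intensity trend, robust estimation, array weights, other thresholds, 1 value per gene, only the arrays of 1 time, the block, and leaving out each array. A group left with 1 array was assumed to vary like the other groups. Array pairs of a group correlated between 0.968 and 0.987, and no 2 arrays were identical. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.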

Results

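Leaf transcripts of tomato plants sprayed with neutralized phosphorous acid (NPA) or with water were measured on Affymetrix Tomato Genome arrays. NPA is phosphorous acid brought to pH 6.3 with potassium hydroxide, here at 1 g of the acid per litre. Leaves were harvested 6 h and 12 h after spraying, which gave 4 groups of 2 arrays. Each array carried RNA pooled from 5 plants, and the arrays of a group came from separate repeats of the experiment. Values are log2 expression values as deposited. Of the 8404 probe sets tested, 753 had a gene symbol, for 688 genes, and 7651 were unnamed. Changes are differences of group means with a standard error (SE) from limma. The number of arrays limits their precision. Hour of day and time after spraying ran together in this design.

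The first question was which transcripts differed between NPA and water plants 6 h after spraying. RNALE, an S-like ribonuclease known from phosphate starvation and wounding, rose by 2.75 on the log2 scale (SE 0.27, n = 2 per group), a 6.7-fold difference (adjusted p = 0.04). AOS, allene oxide synthase of the jasmonate pathway, rose by 2.36 (SE 0.25, 5.12-fold, adjusted p = 0.04). SPM1 rose by 1.81 (SE 0.11, 3.49-fold, adjusted p = 0.0125). These 3 genes were higher in the NPA array of both repeats, RNALE by 3.25 and 2.24, AOS by 2.63 and 2.08, and SPM1 by 1.80 and 1.81. The other probe sets that passed were unnamed, with the largest rises at 3.20 and 2.74 and the falls at -1.26 and -1.17.

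In all, 12 probe sets were higher and 2 lower under NPA at 6 h, and with the repeat as a block 81 were higher and 27 lower, including all 14. At an unadjusted p under 0.05 there were 1319, against 420 by chance, and 2069 with the block. Among the named genes that passed with the block and not without it were ACO4, an ACC oxidase of ethylene synthesis, at 0.87 (adjusted p = 0.0332 with the block, 0.0757 without), and ODC, ornithine decarboxylase of polyamine synthesis, at 1.69 (0.0494 and 0.109). PTI5, an ERF transcription factor, stood at 3.98 (0.0494 and 0.137), an arginase probe set, ARG2, at 2.25 (0.0278 and 0.109), and a LOC543955 probe set at 1.86 (0.0452 and 0.299), while the other probe set of LOC543955 stood at -0.01. This ARG2 probe set was chosen after its values were seen. The other named genes that passed as higher only with the block lie outside the naming rule at 6 h. They were ODD at 2.565 (0.0222 and 0.15), Xegip at 1.135 (0.0278 and 0.157) and GST-T4 at 1.835 (0.0443 and 0.22). An adc1 probe set stood at 0.975 (0.0494 and 0.138) and krp2 at 0.755 (0.0494 and 0.114). The named genes with the smallest p among those lower under NPA did not pass without the block: LOC778242 at -1.01 (adjusted p = 0.114), LOC100037511 at -1.63 (0.114), LOC543710 at -0.55 (0.122), PDS, the carotenoid enzyme phytoene desaturase, at -0.58 (0.122), and MFP1 at -0.89 (0.122). With the block LOC778242 passed (0.0494).

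The count of 14 fell to 0 without the first water 6 h array, the second water 6 h array or the second NPA 6 h array, and to 1 without the first NPA 6 h array. It was 8 without either water 12 h array and 22 without either NPA 12 h array. RNALE, AOS and SPM1 stayed higher under NPA, and all 3 lost the call without any 1 of the 6 h arrays, with adjusted p from 0.0732 to 0.32. RNALE and AOS also lost it without either water 12 h array (0.0708). With only the 6 h arrays all 3 had adjusted p = 0.0549, and with an intensity trend AOS had 0.0751.

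**Figure D1:**
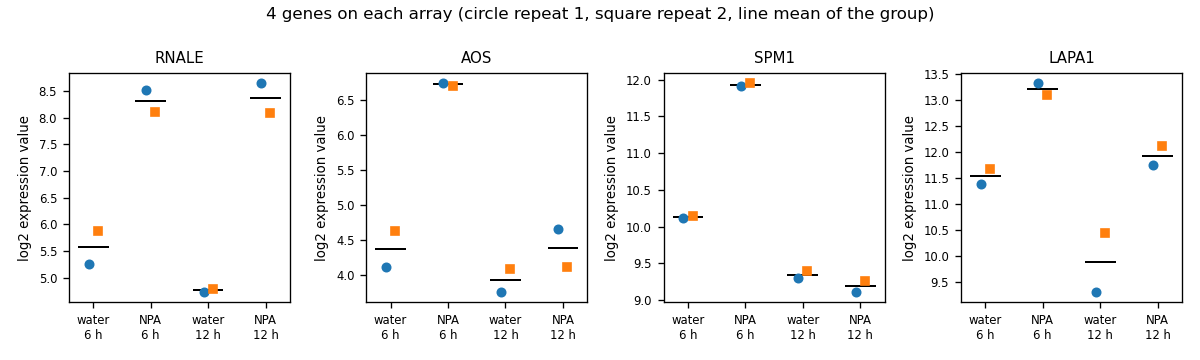
Log2 expression of RNALE, AOS, SPM1 and LAPA1 on each of the 8 arrays, by treatment and harvest, with a circle for repeat 1, a square for repeat 2 and a line at the mean of the 2 arrays. RNALE averages 8.31 at 6 h and 8.37 at 12 h under NPA against 5.56 and 4.76 in water, while the SPM1 means at 12 h are 9.18 under NPA and 9.35 in water.

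Transcripts of pathogenesis-related (PR) proteins were higher as a group at 6 h in the test at the preset correlation of 0.01. Of the 13 measured genes, 12 were above water in both repeats, with a median difference of 2.78 (camera adjusted p = 0.00948). With the correlation estimated, at 0.781 for this list, the adjusted p was 0.44, and with fry it was 0.242. No member passed among all probe sets, and adjusted over the list alone 5 rose and 1 fell. Among these, CHI14 stood at 3.25 (SE 0.75), P69B, a subtilase, at 2.78 (SE 0.74) and LOC543878 at 2.95 (SE 0.92), and the chitinase gene CHI17 at -0.81 (SE 0.21). The group median was 3.97 in repeat 1 and 1.02 in repeat 2. The call was lost without the first water 6 h array (adjusted p = 0.0556) or the first NPA 6 h array (0.0632), and with only probe sets above the median level (0.243).

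**Figure D2:**
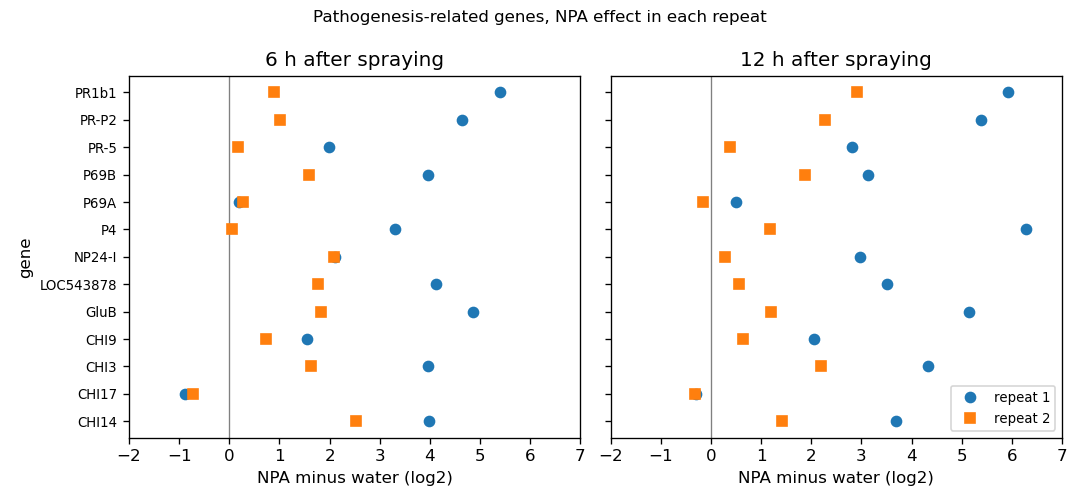
NPA minus water log2 difference of the 13 PR genes at 6 h and at 12 h, with a circle for repeat 1 and a square for repeat 2. PR1b1 lies at 5.39 in repeat 1 and 0.90 in repeat 2 at 6 h, and CHI17 lies below 0 in every pair.

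All 6 WRKY genes, a family of transcription factors, were above water on average at 6 h, 5 of them in both repeats, with a median of 0.44 (adjusted p = 0.025, and 0.338 with an estimated correlation). Adjusted over the list alone, 3 rose, LOC543856 at 0.55, WRKYIId-4 at 0.65 and LOC543855 at 0.54. With the block the adjusted p of the list was 0.0577. It was 0.105 without the first water array and 0.0559 without the second NPA array of 6 h, and 0.0658 without either NPA 12 h array. The 14 ERF genes had a median of 0.29 (adjusted p = 0.0637), and adjusted over the list alone 3 rose: PTI4 at 0.82, PTI6 at 1.62 and PTI5 at 3.98.

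Of the 10 jasmonate genes, 9 were above water at 6 h with a median of 0.39, and the list did not pass (adjusted p = 0.0637). AOS passed among all probe sets. Adjusted over the list alone 3 rose, AOS, AOC at 0.97 and OPR3 at 0.54, all enzymes of jasmonate synthesis, and opr2 fell, at -1.17. The 18 ethylene genes had a median of 0.22 (adjusted p = 0.125), and adjusted over the list alone only ACO4 rose. The ethylene list passed without the second water 6 h array (0.0459) or the first NPA 6 h array (0.038), and without the latter the jasmonate list passed as well (0.038). MTS1, the 1 measured marker of glandular trichomes, stood at 1.51 at 6 h (adjusted p = 0.137) and 0.21 at 12 h (adjusted p = 0.875).

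The other lists fixed beforehand did not pass against the named genes at 6 h. Medians were 0.34 for 8 MAP kinase, calcium and resistance genes (adjusted p = 0.0637, and 0.0168 without the second water 6 h array), 0.59 for 4 phenylpropanoid genes (0.125) and 0.32 for 3 salicylic acid genes (0.283). They were 0.06 for 5 phosphate starvation genes (0.337), 0.61 for 4 redox genes (0.44), 0.36 for 5 heat shock genes (0.29) and 0.22 for 5 ribosomal protein genes (0.283). Auxin genes had a median of -0.25 (0.188), photosynthesis genes of -0.03 (0.522) and histone and cell cycle genes of 0.07 (0.96). Lists with 1 or 2 measured genes were not tested, and their largest differences at 6 h were LAPA1, a leucine aminopeptidase of the wound response, at 1.68, LE16 at 0.91, GAI at -0.47, CELLULASE at -0.43, CHS1 at -0.18 and HMGR at 0.04.

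Other list tests called more groups at 6 h. Against all probe sets, a background chosen after seeing the data, the ERF, jasmonate and MAP kinase lists passed (adjusted p = 0.0111 each), as did ethylene (0.0218) and phenylpropanoid genes (0.0431). With only probe sets above the median level ethylene (0.0313) and jasmonate genes (0.0499) passed. With fry jasmonate (0.0271), ERF, MAP kinase and phosphate starvation genes (0.0385 each) passed, and none of these lists did with an estimated correlation.

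The second question was which transcripts differed 12 h after spraying. RNALE was the 1 probe set past the threshold, higher by 3.61 under NPA (SE 0.27, 12.2-fold, adjusted p = 0.0483) and above water in both repeats, by 3.91 and 3.30. LAPA1 stood at 2.05, FLACCA at 0.95, ARPI at 1.01 and LOC543641 at 0.90, each with adjusted p = 0.46. Below water stood LOC544187 at -1.45 and ETR6, an ethylene receptor, at -0.47 (each 0.46), BL3 at -0.37 (0.48), CAB5, a chlorophyll a/b-binding protein, at -0.86 (0.488), and the second LOC543955 probe set at -0.33 (0.494), while the first stood above water, at 0.74 (0.778). With the block no probe set passed in limma, where 1537 had an unadjusted p under 0.05 against 811 without it, and RNALE had adjusted p = 0.158. With array weights RNALE had 0.0815, and with only the 12 h arrays 0.391. Leaving out any 1 array other than the second NPA 12 h array gave 0, and leaving out that array gave 3.

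At the preset correlation PR genes were higher as a group at 12 h too. Of 13, 12 were above water, with a median of 2.51 (adjusted p = 4.91e-05, 0.622 with an estimated correlation and 0.412 with fry). Adjusted over the list alone 4 rose, PR1b1 at 4.42, CHI14 at 2.55, P69B at 2.51 and CHI9 at 1.35. The median was 3.52 in repeat 1 and 1.17 in repeat 2, and with only probe sets above the median level the list had adjusted p = 0.112. The 5 phosphate starvation genes had a median of 0.57 (adjusted p = 0.0345, and 0.497 with an estimated correlation), and adjusted over the list alone RNALE and PAP1, at 0.92, rose. The 3 genes of the salicylic acid list had a median of 0.36 (adjusted p = 0.0406, and 0.497 with an estimated correlation). NPR1, a receptor of salicylic acid, stood at 0.60 and was the 1 member that rose adjusted over the list alone. GPA1, at 0.36, is a G protein alpha subunit that entered the list through its synonym TGA1. Its value is the list median here, and without it the list, also at 6 h, falls below the 3 genes needed for a test. With the block both lists had adjusted p = 0.0919. Without the first or the second water 12 h array the phosphate list had adjusted p = 0.102 and 0.0657, and without the second NPA 12 h array 0.248. It was 0.0607 without either NPA 6 h array. For the salicylic acid list the values without the first and second water 12 h array were 0.102 and 0.111, without the first and second NPA 12 h array 0.145 and 0.153, and without either NPA 6 h array 0.0607.

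No other fixed list passed at 12 h. Medians were -0.10 for jasmonate (adjusted p = 0.714), -0.16 for ethylene (0.113), -0.03 for ERF (0.767), 0.01 for WRKY (0.79), -0.06 for photosynthesis (0.113) and -0.21 for auxin genes (0.113). They were 0.16 for phenylpropanoid (0.45), 0.38 for redox (0.679), 0.09 for MAP kinase, calcium and resistance (0.703), 0.11 for ribosomal protein (0.79), -0.02 for histone and cell cycle (0.79) and 0.00 for heat shock genes (0.965).

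Averaged over both times, 6 probe sets were higher and none lower in limma, against 989 at an unadjusted p under 0.05 and 1680 with the block. RNALE was higher by 3.18 (SE 0.19, adjusted p = 0.00792) and SPM1 by 0.82 (SE 0.08, adjusted p = 0.0463). With the block 73 were higher and 7 lower. AOS (1.41, adjusted p = 0.0463 with the block and 0.0966 without), LAPA1 (1.87, 0.0381 and 0.124), LOC543954 (1.66, 0.049 and 0.14) and the first LOC543955 probe set (1.30, 0.049 and 0.413) then passed, as did MT3 in the other direction (-0.54, 0.049 and 0.325). LOC544187 (-0.88), SBT1 (-0.64), LOC778242 (-0.48), gMDH (-0.31) and CHI17 (-0.56) passed in neither fit. The PR list had a median of 2.65 (adjusted p = 3.06e-05, and 0.403 with an estimated correlation), and the call was also lost with fry (0.0956) and with only probe sets above the median level (0.153). Against all probe sets 7 more fixed lists passed, with adjusted p from 0.0101 to 0.0469, and with fry the phosphate starvation list did (0.0119). The count of 6 became 0 without the first water 6 h or the first water 12 h array, and 1 without the first NPA 6 h array. It became 2 without the second water 6 h, the second NPA 6 h or the first NPA 12 h array, 11 without the second water 12 h array and 49 without the second NPA 12 h array.

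The third question was whether the NPA effect differed between 6 h and 12 h. SPM1 came closest among the named genes, with an effect of 1.81 at 6 h and -0.16 at 12 h (difference -1.97, SE 0.16, adjusted p = 0.0761). The AOS effect was 2.36 and 0.47 (difference -1.89, adjusted p = 0.185). ODC differed by -1.68, krp2 by -0.91 and ACO4 by -0.73. Differences in the other direction were 2.72 for LOC100037511, 1.73 for LOC543829, 1.41 for MFP1, 1.01 for LEJA1 and 0.88 for PDS. No probe set passed in limma, with or without the block, while 1123 had an unadjusted p under 0.05 without the block, against 420 by chance, and 1864 with it. Without the first NPA 6 h array 1 passed. Over all probe sets the effects at 6 h and 12 h correlated at 0.632 in repeat 1 and at -0.155 in repeat 2.

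As groups, 4 fixed lists had smaller effects at 12 h than at 6 h. The median difference was -0.56 for jasmonate genes, -0.42 for ethylene genes and -0.46 for WRKY genes (adjusted p = 0.0186 each), and -0.56 for ERF genes (0.0424, and 0.0687 with the block). With an estimated correlation the adjusted p was 0.356 for jasmonate, ERF and WRKY genes and 0.441 for ethylene genes. With fry it was 0.065 for jasmonate, 0.144 for ERF and 0.146 for ethylene and WRKY genes. ERF genes also had 0.167 with only probe sets above the median level and 0.0622 against all probe sets. The PR list did not pass this test (median difference 0.21, adjusted p = 0.777). From 6 h to 12 h the ERF median changed by 0.723 in water and 0.043 in NPA plants, and the ethylene median by 0.393 and 0.157. For these 2 lists the difference thus came with a rise in water plants and not with a fall under NPA. WRKY genes had 0.25 and -0.072, and jasmonate genes -0.595 and -0.935. The 6 h effect, the difference and the time change in water all use the water 6 h arrays.

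These 4 calls depended on single arrays. Without the first water 6 h array each list had adjusted p = 0.0649. Without the second water 12 h array jasmonate genes had 0.108, ethylene genes 0.0542, and ERF and WRKY genes 0.12. Without the first NPA 12 h array WRKY genes had 0.135 and the other 3 lists 0.0644. Without the second NPA 6 h array jasmonate genes had 0.0956 and ethylene genes 0.111, and without the first ERF genes had 0.131 and WRKY genes 0.052. ERF genes also had 0.0691 without the second water 6 h array and 0.0821 without the second NPA 12 h array. Without that last array the PR list passed, with adjusted p = 0.00476.

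The last question was how leaf transcripts changed from 6 h to 12 h. In water plants TBG3, a beta-galactosidase, rose by 4.34 (SE 0.55, adjusted p = 0.00487) and Psy1, a phytoene synthase, by 3.45 (SE 0.40, adjusted p = 0.00374). LePCL1 (2.13), GBF12 (2.05) and LOC778326 (1.68) rose as well. CIP1 fell, at -5.28 (SE 0.29), as did ZEP, zeaxanthin epoxidase, at -4.86 (SE 0.28), CAB5 at -4.55 (SE 0.27), fsm1 at -3.46 and PPCK1 at -2.77. Of the 8404 probe sets 981 rose and 886 fell, and with the block 1697 rose and 1447 fell. Falls outnumbered rises with each array centred on its median (863 rises, 981 falls) and with a fold minimum of 2 (329 and 372). The count of 1867 was 356 and 639 without the first and second water 6 h array and 818 and 689 without the first and second water 12 h array, with more falls than rises in each.

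Of 8 photosynthesis genes 3 fell in water plants, CAB5, CAB4 at -2.32 and CAB6A at -1.85, while the list did not pass (adjusted p = 0.349). Ethylene genes were higher at 12 h with a median of 0.39, and 7 of 18 rose, ETR4 by 1.53, EIL1 by 0.88, EIL3 by 0.90 and ACO6 by 0.60 among them (adjusted p = 0.0131, and 0.699 with an estimated correlation). ERF genes had a median of 0.72, with PTI4 up by 1.07 and JERF1 by 0.87 (adjusted p = 0.0449, and 0.644 with an estimated correlation). The ERF call was lost without the second water 6 h array (0.12) or the second water 12 h array (0.197), and against all probe sets neither list passed (0.063 for ethylene, 0.131 for ERF). With fry photosynthesis (0.00151), jasmonate and phosphate starvation genes (0.0173 each) passed as lower at 12 h.

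In NPA plants 1195 probe sets rose and 988 fell from 6 h to 12 h, with the block 1826 and 1575, and with a fold minimum of 2 fewer rose (371) than fell (439). TBG3 rose by 4.46, Psy1 by 3.19, GBF12 by 2.25 and TDR6 by 2.24. CIP1 fell, at -5.40, as did CAB5 at -5.33, ZEP at -4.28, fsm1 at -3.74 and SPM1 at -2.75. Water and NPA plants shared 565 rises, where 139 are expected of independent lists, and 593 falls, where 104 are expected. No fixed list passed in NPA plants with camera, although the PR list did without the second NPA 12 h array (adjusted p = 0.018), and of 10 jasmonate genes 4 fell (list median -0.94, adjusted p = 0.166). With fry photosynthesis (0.000815), jasmonate (0.002) and heat shock genes (0.0431) passed as lower at 12 h. The count of 2183 was 943 and 1057 without the first and second NPA 6 h array and 925 without the second NPA 12 h array, 422 rises and 503 falls.

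Poly-A control signal, a measure of labelling added to the RNA, was lower on the second water 6 h array (7.22) and on the NPA 12 h arrays (7.07 and 6.85) than on the other 5 arrays (7.77 to 7.96). Without these 3 arrays, a choice made after seeing the data, no probe set passed at 6 h and 422 passed between 6 h and 12 h in water, 174 as rises and 248 as falls.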

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

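Tests chosen only after the result was seen were those of a weaker response in repeat 2, of the hybridization controls, of the order of PR genes and controls, of a general loss of signal at 12 h and of members varying together, and the wider set of probe sets below was added after as well.

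The effect of NPA on 5 gene groups differed between 6 h and 12 h by a camera test of the difference at the preset correlation. Medians were -0.557 for jasmonate, -0.418 for ethylene, -0.562 for ERF, -0.455 for WRKY and 0.442 for carotenoid genes. The carotenoid list was written after the gene names were seen. No call held with an estimated correlation (adjusted p = 0.235 for carotenoid genes, 0.356 to 0.441 for the others) or with fry (0.0783, and 0.065 to 0.146). A loss of NPA signal at 12 h in all genes is argued against by the PR list, whose median at 12 h was 0.903 of that at 6 h and whose members changed by a median of 0.205 (SD 0.832), where halving needs -1.39, but a loss in part of the transcripts stays open, as fewer probe sets had an unadjusted p under 0.05 at 12 h (811) than at 6 h (1319). Members that vary together remain a candidate explanation for ethylene and WRKY genes, which at their own estimated correlations, 0.103 and 0.1, had adjusted p = 0.176 and 0.056. Jasmonate and ERF genes passed at theirs, 0.02 and -0.016, the latter taken as 0 (adjusted p = 0.0237 and 0.0269), though not with every list at its own (0.0538 each), and on 4 residual degrees of freedom the upper bounds of 0.626 and 0.264, at which neither passed, leave it open for them too. Time after spraying stays open and runs together with hour of day.

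PR genes responded more in repeat 1 than in repeat 2 (median difference 2.12, 12 of 13 genes). The camera adjusted p was 6.88e-10 at the preset correlation and 0.622 with an estimated one, and no single probe set passed. Higher PR levels in the water plants of repeat 2 are argued against as the whole cause. Averaged over both times those levels differed by a median of 0.075 (SD over members 0.499), with 9 of 13 higher in repeat 2. Levels under NPA differed by -1.89, with 13 of 13 lower in repeat 2. At 6 h alone all members but CHI17 and P69A were higher in those water plants, GluB most, at 7.54 against 5.87. A part in the 6 h difference stays open. Normalization is argued against by the hybridization controls and by the order of values. Probe sets of like level, 5178 of the 8404, had a median difference of 0 (SD 0.302). That median decides nothing, since scaling holds the median of most probe sets near 0. The 18 hybridization controls had -0.005, none beyond 0.13, and scaling keeps the order of values on an array. On the NPA arrays 9 of 13 members lay above a control in repeat 1 and below it in repeat 2. Each did so by over 0.71, the largest move of a control between repeats. On the water arrays 1 did, which says little, since most members lay below the lowest control mean of 8.34 there and could not cross. A weaker response of all genes in repeat 2 stays open: 5 jasmonate and wound genes had a median ratio of repeat 2 to repeat 1 of 1.02 against 0.411 for PR genes, but 597 probe sets outside the list with an effect above 0.5 had 0.676, and no biological explanation was tested.

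The averaged NPA effect was set against other splits of the 8 arrays into 4 and 4, of which 34 of 35 could be fitted. As many probe sets as the real 6 were called in 2 of 34 splits, the real one included, so chance is not excluded without the block. The other split was the repeats themselves, with 55, which points to a structure of the samples by repeat, and every remaining split gave 0. A simpler model without the interaction, run first, gave 2 for the real split, 53 for the repeats and again 2 of 34. With the repeat as a block the real split gave 80 and the highest other split that parts each repeat evenly gave 0, and 16 such splits are too few for a share under 0.05.

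Several named genes lay on opposite sides of water at the 2 times on all arrays, with differences of effect that did not pass the test (adjusted p from 0.0761 to 0.222). These were -1.965 for SPM1, 2.72 for LOC100037511, 0.65 for LOC543710, 0.88 for PDS, 1.405 for MFP1, -0.69 for ETR6, 1.73 for LOC543829, 1.01 for LEJA1 and -0.905 for krp2. The differences of 2 unnamed probe sets were 1.46 and 1.43.

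A control probe set left out of the comparisons, GlutTrans_3, was higher under NPA at 6 h by 1.795 (adjusted p = 0.0371), in both repeats. Of its sibling probe sets GlutTrans_5 stood at 0.34 (0.585) and GlutTrans_M at 1.545 (0.0608, and 0.0427 with the block). The meaning of these names is not given in the sources used here.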

How the results depend on the processing

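Fits without low poly-A arrays, lists against all probe sets, and lists after quantile normalization or centring were tests chosen only after the data were seen. No called gene or list reversed, while the balance of rises and falls between the times turned in fits given in the report. Of the values followed for named genes and listed unnamed probe sets, 253 kept their status, passed or not, 18 lost and 11 gained a call. With 1 array left out 207 kept their status, 45 lost and 4 gained a call. Most values that kept their status had not passed in the main fit, so these numbers do not count calls that held. Of list values 1111 kept their status, called or not, 48 lost and 41 gained a call, and 42 that passed in neither fit changed direction. With 1 array left out these numbers were 1124, 45, 26 and 101. Counts for NPA at 6 h, at 12 h, averaged, the difference, and time in water and in NPA were 14, 1, 6, 0, 1867 and 2183. With the replicate block they were 108, 0, 80, 0, 3144 and 3401, and the block changed no list call other than those given here, in the report and under other observations. Quantile normalization again gave 2 for the difference. Probe sets above the median level, fewer of which were tested, gave 5 at 6 h, 0 at 12 h, 1 for the difference, 1157 in water and 1281 in NPA. Those above the first quartile gave 6, 0, 3 averaged and 1 for the difference. An intensity trend gave 9, 2 and 1 for the difference, and array weights 0 at 12 h. A fold minimum of 2 gave 701 in water and 810 in NPA. Adjusted p under 0.10 gave 12 averaged and 1 for the difference. Unadjusted p with that minimum gave 223, 91, 137, 272, 795 and 900. The arrays of 1 time alone gave 2 at 6 h and 0 at 12 h, from fewer arrays. Without low poly-A arrays 0 passed at 6 h and 422 in water. Except where fewer arrays or probe sets were used, the cause was not tested.

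Leaving out 1 array gave 0 to 22 at 6 h, 0 to 3 at 12 h, 0 to 49 averaged, 0 to 1 for the difference, 356 to 1740 in water and 925 to 1892 in NPA. List adjusted p then ran from 9.95e-05 to 0.0632 (PR, 6 h), 3.68e-09 to 0.0239 (PR, 12 h), 0.0026 to 0.105 (WRKY), 0.00323 to 0.248 (phosphate), 0.0407 to 0.153 (salicylic acid), 4.94e-05 to 0.0148 (carotenoid), 0.0154 to 0.175 (photoreceptors), 0.00012 to 0.037 (wound, 6 h) and 6.71e-10 to 0.0292 (wound, 12 h).

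No list call held with an estimated correlation. At 6 h and 12 h the adjusted p was 0.44 and 0.622 for PR and 0.34 and 0.375 for wound genes. It was 0.338 for WRKY, 0.497 for phosphate and salicylic acid, 0.26 for carotenoid and 0.587 for photoreceptor genes. Correlation among a list's own members cannot be the whole cause. Phosphate and ERF genes were estimated at -0.075 and -0.016, below the preset of 0.01. ERF genes still went from 0.0424 to 0.356 for the difference. With every list held at its own estimated correlation, ERF and jasmonate genes had 0.0538 each, WRKY genes 0.0747 and ethylene genes 0.176. The test with an estimated correlation gave 0.356 for ERF, jasmonate and WRKY genes and 0.441 for ethylene genes. That test thus differed in more than the correlation, and its values do not measure correlation alone. With fry PR had 0.242 and 0.412, salicylic acid 0.093, photoreceptors 0.241 and wound genes at 12 h 0.0583, and fry ended the calls for the difference as given above. The replicate block gave 0.0577 for WRKY and 0.0919 for phosphate and salicylic acid. Above the median level PR had 0.243 and 0.112 and photoreceptors 0.3. Photoreceptors had 0.0922 against all probe sets and 0.0553 with centring. Without detection calls, the signal over background that limits dim probe sets is unknown.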

Other observations

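The test of a phosphate starvation type response was chosen only after the result was seen, and the lists described here were written after the gene symbols had been seen. Wound-response genes were higher under NPA at 6 h, with 4 of 5 above water in both repeats and a median of 1.77 (camera adjusted p = 0.01, and 0.34 with an estimated correlation). Adjusted over the list alone 4 rose, cathDInh at 2.48, TD2, threonine deaminase, at 1.96, ARG2 at 1.77 and LAPA1 at 1.68. At 12 h all 5 were above water, with a median of 1.61 (adjusted p = 0.000508, and 0.375 with an estimated correlation). Carotenoid and plastid isoprenoid genes were lower at 6 h, with 12 of 16 below water in both repeats and a median of -0.37 (adjusted p = 0.000356, and 0.26 with an estimated correlation). Of these PDS, CRTL-E-1 at -0.53 and PSY2 at -0.57 fell adjusted over the list alone. At 12 h the median was 0.10 (adjusted p = 0.327).

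Photoreceptor and light signalling genes had a median of -0.25 at 6 h (adjusted p = 0.0487, and 0.587 with an estimated correlation). That call was lost without the second water 6 h array (0.161), the first NPA 6 h array (0.175) or either water 12 h array (0.0607). Nitrogen, amino acid and polyamine genes had a median of 0.21 (adjusted p = 0.0827, against all probe sets 0.0164 and with fry 0.00587), and adjusted over the list alone ODC at 1.69 and an adc1 probe set at 0.93 rose. The remaining lists did not pass at 6 h without the block. Cell wall genes had a median of -0.15 (adjusted p = 0.0606, and 0.0675 averaged over both times). With the block they passed (0.0288 and 0.0328), though not with an estimated correlation as well (0.317 and 0.282). The others were antioxidant (-0.01, 0.603), sugar and starch (-0.02, 0.969), 14-3-3 (0.17, 0.603), cell cycle (-0.13, 0.969), phospholipase D (0.27, 0.499), phosphate response (0.09, 0.66) and protease genes (0.06, 0.969). From 6 h to 12 h in water, sugar and starch genes had a median of -0.49, with hxk1 at -1.47 among those that fell, and phosphate response genes of -0.57 (adjusted p = 0.0366 each, and 0.789 and 0.508 with an estimated correlation). With the block the adjusted p was 0.0614 and 0.0676, without the second water 6 h array 0.0719 for both, and without the second water 12 h array 0.0702 and 0.0574. Sugar and starch genes also had 0.296 with only probe sets above the median level. With fry carotenoid and nitrogen genes (0.00986 each) passed as lower at 12 h in water and 14-3-3 genes (0.0258) as higher, and carotenoid genes also did with only probe sets above the median level (0.0229). In NPA plants nitrogen (0.00263) and phosphate response genes (0.0104) passed with fry as lower. At 12 h phosphate response genes, RNALE among them, had a median of 0.323 against water (adjusted p = 0.0808, against all probe sets 0.0119 and with fry 0.0158).

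RNALE was higher under NPA at both times, and a hypothesis is that NPA may set off a phosphate starvation type response. Of the 4 other measured genes of that list, 1 was higher in both repeats at both times, PT1 (0.86 and 0.60 at 6 h, 0.75 and 0.39 at 12 h), and TPSI1 was lower in both repeats at 6 h. Without RNALE the list did not pass at 6 h (median 0.015, adjusted p = 0.96) or at 12 h (0.323, adjusted p = 0.405), though PAP1 rose at 12 h adjusted over the full list alone. With 4 genes that go both ways (SD over them 0.527 at 6 h and 0.471 at 12 h), a phosphate starvation type response stays open.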
